A study of Mus musculus with 6 samples.

How the data were processed

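RNA was sequenced from the mouse embryonic stem cell line E14TG2a at 3 stages of neuronal differentiation, with 2 libraries for each of the groups mESC, NPC and NC. Per the labels, the stem cells grew on gelatin without feeder cells in medium with serum and LIF, and the differentiation followed a published protocol for making neurons from stem cells. The libraries were made from poly(A)-enriched and rRNA-depleted RNA with an Ion Total RNA-Seq kit and sequenced on an Ion Proton. The cell type label of all 6 samples reads embryonic stem cells, so the groups were taken from the sample titles, with NC placed as the stage after NPC. Samples with the same replicate number in different groups are not said to share a culture or a day.

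The authors' notes name FastQC, cutadapt 3.4, STAR 2.7.9a, StringTie 2.1.5, R 4.0.3 and DESeq2 without their order or settings, and give the genome build as mm10. Each deposited table has the header of StringTie's gene abundance output, with 1 table per library. The deposited coverage is StringTie's mean read depth over the exons of a gene, not scaled to the depth of the library. The deposited FPKM values are StringTie's abundance per length of transcript, scaled to the aligned bases of the library. The deposited TPM values are StringTie's rescaling of FPKM to the same sum in each library. Annotation release and strand settings are not given in the sources used here. The tables hold no read counts. For 38.3% to 39.7% of the genes with FPKM of at least 1 the ratio of coverage to FPKM was 1 constant per library, within a tolerance of 0.1%, and this constant gives the aligned bases in Gb. It lay between 1.57 and 2.27 Gb. Without counts no counting interval or detection limit can be given, and the precision of a value is given by its 2 replicates.

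Each table lists 46517 gene IDs. Between 2 and 9 repeated lines of a gene ID per table were summed. Of the IDs, 27555 matched GENCODE vM21 with version, all 27555 of these with the same start and end, and 46005 matched without version. Biotypes come from that annotation. The 83 symbols carried by more than 1 gene ID were kept apart by ID. All 37 genes of the mitochondrial chromosome are at 0 in all 6 tables. Symbols and positions are those of the tables.

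Genes with TPM of at least 1 in at least 2 of the 6 libraries were tested. The test was limma 3.58.1 in R 4.3.3, with lmFit and eBayes with a trend on log2(TPM + 1). It was fitted to all 6 libraries with 1 coefficient per group and no replicate block, which leaves 3 residual degrees of freedom before moderation. The contrasts NPC against mESC, NC against NPC and NC against mESC were two-sided, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Means and SDs in the text are of TPM, while log2 fold changes and their SEs come from the fit. A gene with a library at 0 is given by its value in each library, and no fold is given against a group at 0 in both libraries. A group of 2 libraries allows no permutation test with p under 0.05. On simulated data with the observed spread and 20232 genes, limma recovered 43 of 100 genes changed by a log2 fold of 1 and 95 of 100 changed by a log2 fold of 2, and 7.4% of its calls were false.

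Before the data were examined, 35 lists of 480 genes were fixed, of which 437 were tested. They cover pluripotency, germline, neural progenitor, neuron and transmitter genes, markers of other cell types, Hox and retinoic acid genes, and genes of the cell cycle, DNA methylation, chromatin, imprinting, splicing, stress and glycolysis. Lists with at least 3 tested members were tested with camera from limma at a preset correlation of 0.01, two-sided and adjusted over 102 tests of lists and contrasts, of which 61 passed. With an estimated correlation 0 passed by camera (smallest adjusted p = 0.104), and 17 had an unadjusted p under 0.05. In this form the test rests on the 3 residual degrees of freedom, which limits how small its p can become. The estimated correlation of the pluripotency list was -0.013, below the preset. Its camera p in NPC against mESC still went from 8.52e-24 to 0.00154. The loss of a call therefore does not by itself show correlation between members. The estimates ranged from -0.023 (oligodendrocyte) to 0.803 (endoderm), with 0.636 for replication, 0.593 for glycolysis and 0.331 for proneural genes. For lists with an estimate well above the preset, the p at the preset can be too small. Counts of members that rose or fell use the p adjusted over all tested genes, and counts adjusted over the list alone stand beside them. Genes higher in NPC than in both other groups are those called in both contrasts, and their overlap with lists was tested by Fisher's exact test, adjusted over the lists. With no effect, 100 simulations gave a highest count of 0 such genes. No gene changed in these simulations, so they do not give the count expected where many genes change.

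The genes named were chosen by a rule fixed at the same time. Per comparison it takes the 6 called genes with the highest and the 6 with the lowest log2 fold change. These need both libraries of one group above both of the other, a mean of at least 10 TPM in the higher group and a symbol that is not a gene-model name. It adds up to 4 called members of each described list with the largest change or, with none called, the most abundant member. It also adds Pou5f1, Nanog, Pax6, Nes, Sox2, Tubb3, Map2, Slc17a6, Gad1, Gfap, Dnmt1, Dnmt3a, Dnmt3b, Tet1, Tet2 and Tet3, and markers of other cell types with a mean of at least 10 TPM in any group. The text names part of the genes the rule allows. Hprt, Unc5a, Eno1b and the genes at the mitochondrial-like locus were named after their values were seen.

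The alternatives tried were pseudocounts of 0.1 and 5, no filter beyond a TPM above 0, a filter at 5 TPM, median-of-ratios scaling and quantile normalization. Further ones were leaving out ribosomal protein genes and the 10 most abundant genes, FPKM, limma without trend, only the 2 groups compared, a replicate block, an added limit of 1 on the absolute log2 fold change, and leaving out each library in turn. Mitochondrially encoded genes were part of the genes to be left out and were already at 0. Protein-coding genes only was added after the data were seen. Gene models of a locus on chromosome 1 were compared with mitochondrial transcripts of GENCODE vM21 by blastn from BLAST 2.17.0 with a largest E value of 1e-20. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for tables and plots.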

Results

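RNA abundance was measured by sequencing in 6 libraries of E14TG2a, a mouse embryonic stem cell line, at 3 stages of its differentiation into neurons. The stages were embryonic stem cells grown without feeder cells in medium with the cytokine LIF (mESC), neuronal progenitors (NPC) and a last stage that the labels call NC. The labels do not spell NC out, and it is taken here as the remaining stage of the study's design text, glutamatergic pyramidal neurons. Each stage had 2 libraries, which the labels describe as biological replicates. Values are deposited TPM, a transcript abundance scaled to the same sum in each library, per gene on the mm10 genome and are given as mean ± SD of the 2 libraries of a stage. The tables hold no read counts, and the ratio of coverage to FPKM put the depth at 1.57 and 2.27 Gb of aligned bases in mESC replicates 1 and 2, 2.25 and 1.99 Gb in NPC, and 1.79 and 2.13 Gb in NC. Genes of at least 1 TPM numbered 17167 and 16667 in mESC, 17740 and 18015 in NPC, and 18599 and 19040 in NC. The log2 difference between the 2 libraries of a stage had an SD over the tested genes of 0.4996 in mESC, 0.406 in NPC and 0.600 in NC, against 0.934 to 1.70 between libraries of different stages. Hprt, a purine salvage gene that is inactivated in E14TG2a, lay between 0.320 and 2.02 TPM in the 6 libraries, a check chosen after its values were seen. All 37 genes of the mitochondrial chromosome were listed at 0 in all 6 libraries. An exact 0 is therefore given only as listed at 0, with no fold against a stage in which both libraries are at 0.

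Neuronal progenitors were compared with the stem cells to ask which genes change over the first step of the differentiation. Most pluripotency genes fell, while most Hox genes, retinoic acid genes, proneural factors and neuron structure genes rose. Pou5f1 (ENSMUSG00000024406.15, chromosome 17, 35506018 to 35510772), which encodes the pluripotency factor OCT4, fell from 1683 TPM ± 294 in mESC to 0.920 ± 0.219 in NPC (n = 2 each, log2 fold change -9.77, SE 0.215, limma adjusted p = 6.31e-06). Cyp26b1 (ENSMUSG00000063415.11, chromosome 6, 84571414 to 84593908), which encodes an enzyme that degrades retinoic acid, rose from 0.509 TPM ± 0.103 to 654 ± 114 (log2 fold change 8.75, SE 0.207, limma adjusted p = 6.42e-06). Neurog1, a proneural transcription factor that commits progenitors to the neuronal fate, rose from 0.208 TPM ± 0.191 to 145 ± 23.4 (log2 fold change 6.92, SE 0.319, limma adjusted p = 3.89e-05).

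Of 20232 genes tested, 8100 changed between NPC and mESC at a Benjamini-Hochberg adjusted p under 0.05 (limma on log2(TPM + 1)), 5268 of them higher and 2832 lower in NPC. At least 2-fold changes on that scale were seen for 3789 of the genes that rose and 1886 of those that fell. The median log2 fold change of all tested genes was 0.18, and -0.02 after median-of-ratios scaling. Genes that rose made up 65.0% of those changed as deposited, 52.4% after that scaling and 51.2% after quantile normalization. The count was 4733 without NPC replicate 1 and 4138 without NPC replicate 2.

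Of the pluripotency genes, 22 of 24 tested fell from mESC to NPC. In the pluripotency list 23 passed adjusted over the list alone (camera adjusted p = 8.69e-22, adjusted p = 0.104 with an estimated correlation). Tdgf1, a co-receptor for NODAL, stood at 852 TPM ± 346.1 in mESC and at 0.0664 and 0 TPM in the NPC libraries (log2 fold change -9.63, SE 0.326, limma adjusted p = 1.94e-05). Zfp42, the stem cell marker REX1, fell from 853 TPM ± 88.8 to 2.15 ± 1.14 (log2 fold change -8.13, SE 0.290). Nanog, a transcription factor of the same network, was at 237 TPM ± 34.0 in mESC and listed at 0 in both NPC libraries (limma adjusted p = 1.43e-05). Sox2, which serves both pluripotent and neural stem cells, fell less far, from 258 TPM ± 1.84 to 79.8 ± 12.03 (log2 fold change -1.69, SE 0.310, limma adjusted p = 0.00608). Outside the lists, Trh, which encodes the precursor of thyrotropin-releasing hormone, fell from 610.7 TPM ± 74.6 to 1.01 ± 0.131 (log2 fold change -8.24, SE 0.206). Tdgf1-ps1 (392 TPM ± 145 in mESC, listed at 0 in both NPC libraries) is a processed pseudogene of Tdgf1, and U3 (ENSMUSG00000104856.1) and Rnu3b4 (309.8 TPM ± 123 and 310.0 TPM ± 122 in mESC, 0 and 0.0728 TPM and 0 and 0.0533 TPM in NPC) are near-identical copies of the U3 small nucleolar RNA, so their values are uncertain. Among genes of the primed epiblast, the state that follows implantation, 2 rose and 3 fell of 10 tested. In the primed epiblast list 2 up and 4 down passed adjusted over the list alone (camera adjusted p = 0.0487, adjusted p = 0.342 with an estimated correlation). The primed epiblast list was not called without mESC replicate 1 (camera adjusted p = 0.0925), without mESC replicate 2 (camera adjusted p = 0.134) and without NPC replicate 1 (camera adjusted p = 0.111), nor under 8 other settings (adjusted p from 0.0519 to 0.0970). Otx2 fell (log2 fold change -3.74), while Cdh2, which encodes N-cadherin, rose (3.80).

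Hox genes, which pattern the head-to-tail axis, were higher in NPC for 18 of 19 tested members. In the HOX list 19 passed adjusted over the list alone (camera adjusted p = 5.30e-14, adjusted p = 0.110 with an estimated correlation). Hoxb6 (ENSMUSG00000000690.5, chromosome 11, 96292476 to 96301569) was at 0 and 0.142 TPM in the mESC libraries and at 592 ± 4.09 TPM in NPC (log2 fold change 9.12, SE 0.150, limma adjusted p = 5.92e-06). Hoxb3 went from 0 and 0.227 TPM to 285 ± 15.0 TPM (log2 fold change 8.01), Hoxb8 from 0.309 TPM ± 0.150 to 329.8 ± 12.8 (7.99) and Hoxd4 from 0.156 TPM ± 0.118 to 254 ± 24.4 (7.79). The antisense gene Hoxb5os, listed at 0 in both mESC libraries and at 248 TPM ± 79.2 in NPC, overlaps Hoxb5 and Hoxb6, and Hoxb3os overlaps Hoxb2 and Hoxb3. Whether the quantification used strand is not given in the sources used here, so each of these values can hold reads of a neighbour. Hoxd4 overlaps Hoxd3 on the same strand, where strand does not separate their reads. The unknown strand setting also bears on 69 of 255 genes picked for description, which overlap a gene model of at least 1 TPM on the opposite strand, among them Nefm, Cbx7, Tagln and Dnmt3l. Of the retinoic acid genes, 11 of 12 tested rose. In the retinoic acid list 12 passed adjusted over the list alone (camera adjusted p = 2.43e-08, adjusted p = 0.167 with an estimated correlation). Besides Cyp26b1 they included Crabp2, which encodes a retinoic acid binding protein (5.11 ± 0.261 to 721 TPM ± 83.9, log2 fold change 6.88, SE 0.184), and Dhrs3, a retinaldehyde reductase (1.15 ± 0.633 to 255 TPM ± 124, log2 fold change 6.84, SE 0.457). Rarb, a retinoic acid receptor, was at 0.594 and 0 TPM in the mESC libraries and at 157 ± 31.2 in NPC (log2 fold change 6.95). Miat, a long non-coding RNA of the nervous system, rose from 0.648 TPM ± 0.296 to 466 ± 108 (log2 fold change 8.14, SE 0.225).

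Neural stem cell and radial glia markers rose for 17 of 19 tested members and 1, Sox2, fell. In the radial glia list 17 up and 2 down passed adjusted over the list alone (camera adjusted p = 1.17e-05, adjusted p = 0.277 with an estimated correlation). Hes5, a Notch target that keeps progenitors dividing, rose from 0.856 TPM ± 0.119 to 323 ± 51.0 (log2 fold change 7.44, SE 0.892), and Pax6, a transcription factor of radial glia, from 15.4 TPM ± 4.61 to 219 ± 53.3 (log2 fold change 3.75, SE 0.414, limma adjusted p = 0.000838). Nes, the intermediate filament nestin, rose from 8.91 TPM ± 2.82 to 106 ± 5.44 (log2 fold change 3.46, SE 0.253, limma adjusted p = 0.000181), and Fabp7, a fatty acid binding protein of radial glia, was listed at 0 in both mESC libraries and at 51.1 TPM ± 24.1 in NPC (limma adjusted p = 0.00135). Of the proneural genes 14 of 15 rose. In the proneural list 14 up and 1 down passed adjusted over the list alone (camera adjusted p = 5.06e-07, adjusted p = 0.288 with an estimated correlation). Neurog2 and Nhlh1, further proneural factors, were listed at 0 in both mESC libraries and stood at 31.6 ± 0.278 and 45.7 ± 12.4 TPM in NPC.

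Many genes of postmitotic neurons were already higher in NPC than in mESC. Of the cytoskeletal, RNA-binding and adhesion genes of neurons 16 of 20 tested rose and 2 fell. In the neuron structure list 17 up and 2 down passed adjusted over the list alone (camera adjusted p = 6.41e-06, adjusted p = 0.288 with an estimated correlation). Nefm, a neurofilament subunit, rose from 0.864 TPM ± 0.376 to 125 ± 5.37 (log2 fold change 6.10, SE 0.278), Map2, a dendritic microtubule protein, from 3.75 TPM ± 0.181 to 107 ± 57.6 (log2 fold change 4.39, SE 0.344, limma adjusted p = 0.000229), and Tubb3, the neuronal beta-tubulin, from 99.98 TPM ± 23.1 to 446 ± 135 (log2 fold change 2.13, SE 0.251, limma adjusted p = 0.00108). Presynaptic genes rose for 13 of 20, led by Snap25 of the vesicle fusion machinery (1.13 ± 0.126 to 31.7 TPM ± 5.76, log2 fold change 3.93). In the presynaptic list 14 passed adjusted over the list alone (camera adjusted p = 0.000341, adjusted p = 0.288 with an estimated correlation). Glutamatergic genes rose for 9 and fell for 2 of 17 tested, with the receptor subunit Gria2 at 0.0194 TPM ± 0.0147 in mESC and 14.1 ± 5.72 in NPC (log2 fold change 3.84). In the glutamatergic list 10 up and 3 down passed adjusted over the list alone (camera adjusted p = 0.0326, adjusted p = 0.549 with an estimated correlation). The glutamatergic list was not called without mESC replicate 1 (camera adjusted p = 0.0929) and without mESC replicate 2 (camera adjusted p = 0.0542), nor under 3 other settings (adjusted p from 0.0521 to 0.0746). Slc17a6, the vesicular glutamate transporter VGLUT2, was listed at 0 in both mESC libraries and stood at 0.380 TPM ± 0.272 in NPC without passing the test. Of the cortical projection neuron factors 6 of 9 tested rose, among them Pou3f2 (log2 fold change 6.20) and Pou3f3 (5.52), which neural progenitors also express. In the cortical projection list 6 passed adjusted over the list alone (camera adjusted p = 0.000791, adjusted p = 0.277 with an estimated correlation). The list's Tbr1, Fezf2, Neurod2, Neurod6 and Emx1 did not pass the filter. Cajal-Retzius markers rose for 7 of 8, with Lhx5 at 0.290 TPM ± 0.222 in mESC and 49.3 ± 19.97 in NPC (log2 fold change 5.24). In the Cajal-Retzius list 7 passed adjusted over the list alone (camera adjusted p = 0.000154, adjusted p = 0.277 with an estimated correlation). Markers of cholinergic, monoaminergic, glycinergic and motor neurons rose for 6 of 9. In the other transmitters list 6 passed adjusted over the list alone (camera adjusted p = 0.0266, adjusted p = 0.288 with an estimated correlation). The other transmitters list was not called without mESC replicate 1 (camera adjusted p = 0.0993) and without NPC replicate 1 (camera adjusted p = 0.0508). GABAergic genes rose for 3 of 9, and Gad1 did not pass (9.15 ± 5.49 in mESC and 9.72 TPM ± 3.17 in NPC, log2 fold change 0.16, SE 0.400, limma adjusted p = 0.785). In the GABAergic list 3 passed adjusted over the list alone (camera adjusted p = 0.361).

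Subunits of the neuronal form of the BAF chromatin remodelling complex rose for 7 of 8 members. In the BAF neuron list 7 passed adjusted over the list alone (camera adjusted p = 0.000926, adjusted p = 0.277 with an estimated correlation). They included the ATPase Smarca2 (1.12 ± 0.631 to 34.3 TPM ± 1.01, log2 fold change 4.09, SE 0.261) and Actl6b (0.296 ± 0.0557 to 13.0 TPM ± 3.02, log2 fold change 3.42, SE 0.232). Of the progenitor-type subunits 2 of 8 rose, Dpf2 (log2 fold change 0.85) and Smarca4 (0.52). In the BAF progenitor list 2 passed adjusted over the list alone (camera adjusted p = 0.914). The BAF progenitor list had a median log2 fold change of 0.047 and a mean of 0.10, while the direction in camera was down. Regulators of neural splicing rose for 9 of 12, among them Srrm4, which promotes neuronal microexons (log2 fold change 3.43), and Nova1 (3.38). In the neural splicing list 9 passed adjusted over the list alone (camera adjusted p = 0.00245, adjusted p = 0.323 with an estimated correlation). Calls were lost without NPC replicate 1 for Smarca4 (limma adjusted p = 0.0883) and without NPC replicate 2 for Dpf2 and Smarca4 (limma adjusted p from 0.0575 to 0.168). Under some settings Smarca4 did not pass (limma adjusted p from 0.0543 to 0.177).

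The title of the series concerns DNA methylation and hydroxymethylation, and the genes that write and remove these marks were compared between mESC and NPC. Of the DNA methyltransferases and their cofactors 6 of 10 fell and 1 rose. In the DNA methylation list 1 up and 6 down passed adjusted over the list alone (camera adjusted p = 0.000396, adjusted p = 0.287 with an estimated correlation). Dnmt3l, a catalytically inactive partner of the de novo methyltransferases, was at 113 TPM ± 39.6 in mESC and 0.294 and 0 TPM in the NPC libraries (log2 fold change -6.60, SE 0.322, limma adjusted p = 4.56e-05). The de novo methyltransferase Dnmt3b fell from 112 TPM ± 0.505 to 19.4 ± 3.10 (log2 fold change -2.48, SE 0.181, limma adjusted p = 0.000181) and Zfp57, which guards methylation at imprinted loci, from 463 TPM ± 26.7 to 72.4 ± 17.5 (log2 fold change -2.68, SE 0.189). The maintenance methyltransferase Dnmt1 was at 209.8 TPM ± 6.54 in mESC and 208 ± 6.49 in NPC (log2 fold change -0.01, SE 0.123, limma adjusted p = 0.957), and neither it nor Dnmt3a passed. Dnmt3a stood at 45.9 and 137 TPM in mESC replicates 1 and 2 and at 61.2 ± 4.95 TPM in NPC (log2 fold change -0.38, SE 0.458, limma adjusted p = 0.560). Its log2 fold change was 0.41 without mESC replicate 2 and -1.16 without mESC replicate 1. The 3 TET dioxygenases, which oxidise methylated cytosine to hydroxymethylated cytosine, went different ways. Tet1 fell from 198 TPM ± 2.55 to 18.96 ± 2.66 (log2 fold change -3.32, SE 0.173, limma adjusted p = 5.70e-05), Tet2 fell from 108 TPM ± 21.4 to 45.0 ± 5.79 (log2 fold change -1.23, SE 0.185, limma adjusted p = 0.00282), and Tet3 rose from 8.68 TPM ± 0.0545 to 57.6 ± 3.96 (log2 fold change 2.60, SE 0.182, limma adjusted p = 0.000154). In the wider demethylation list 5 rose and 5 fell of 12, with the uracil glycosylase Smug1 among those that rose (log2 fold change 3.44). In the DNA demethylation list 6 up and 5 down passed adjusted over the list alone (camera adjusted p = 0.674). The DNA demethylation list had a median log2 fold change of 0.043 and a mean of 0.11, while the direction in camera was down. Methyl-CpG binding proteins rose for 6 and fell for 2 of 10. In the methyl readers list 7 up and 2 down passed adjusted over the list alone (camera adjusted p = 0.115). The methyl readers list was called with no filter beyond a TPM above 0 (camera adjusted p = 0.0359). Polycomb genes rose for 4 and fell for 7 of 17, with the reader subunits going both ways, Cbx7 down (log2 fold change -2.28) and Cbx8 up (2.20). In the Polycomb list 5 up and 7 down passed adjusted over the list alone (camera adjusted p = 0.218). Germline genes whose promoters are known to be silenced by methylation fell for 9 of 10 tested. In the germline list 9 passed adjusted over the list alone (camera adjusted p = 1.44e-06, adjusted p = 0.277 with an estimated correlation). Hormad1, a protein of the meiotic chromosome axis, was at 11.6 TPM ± 1.001 in mESC and listed at 0 in both NPC libraries (limma adjusted p = 0.000117). Rpl10l, a retrogene copy of Rpl10 whose reads can be mistaken for those of the parent gene, fell from 23.6 TPM ± 1.23 to 0.290 ± 0.368 (log2 fold change -4.28). Imprinted genes rose for 14 and fell for 1 of 22, with the fetal growth factor gene Igf2 up (20.3 ± 6.89 to 326 TPM ± 83.8, log2 fold change 3.96), the cell cycle inhibitor Cdkn1c up (3.66) and Phlda2 down (-4.78). In the imprinted list 15 up and 1 down passed adjusted over the list alone (camera adjusted p = 0.00168, adjusted p = 0.288 with an estimated correlation). Dnmt3a passed without mESC replicate 1 (limma adjusted p = 0.00893).

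**Figure D1:**
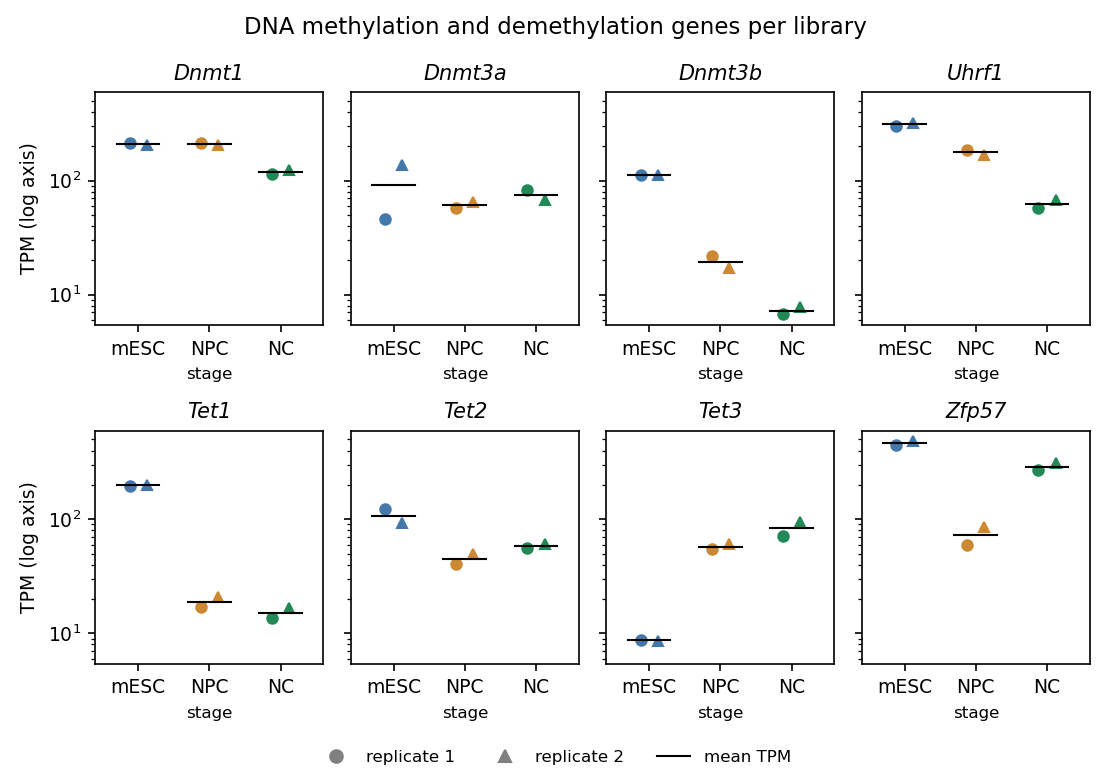
TPM per library, on a log axis, of 8 genes of DNA methylation and demethylation in the 3 stages (points, 2 libraries per stage, and short lines for their mean). Tet1 was at 196 and 199.8 TPM in the mESC libraries and 13.6 and 16.6 TPM in the NC libraries, and Tet3 at 8.72 and 8.65 TPM and 71.6 and 94.6 TPM.

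DNA replication genes fell for 8 of 16 members in NPC, among them Ccne1, cyclin E1 (log2 fold change -1.94), and the licensing factor Cdt1 (-1.37). In the replication list 8 passed adjusted over the list alone (camera adjusted p = 0.000216, adjusted p = 0.461 with an estimated correlation). Mitosis genes fell for 7 of 16, with Ccnb2 (log2 fold change -0.82) and Ccnb1 (-0.81) changed most. In the mitosis list 7 passed adjusted over the list alone (camera adjusted p = 0.000918, adjusted p = 0.288 with an estimated correlation). Immediate early and activity-regulated genes fell for 5 and rose for 1 of 11 tested, led by Arc, which fell from 18.3 TPM ± 4.60 to 1.34 ± 0.0651 (log2 fold change -3.02). In the activity list 1 up and 6 down passed adjusted over the list alone (camera adjusted p = 0.00972, adjusted p = 0.288 with an estimated correlation). Targets of p53 fell for 3 of 12, and these were Perp, Bax and Trp53inp1 (log2 fold changes -1.79, -1.08 and -0.86). In the p53 list 3 passed adjusted over the list alone (camera adjusted p = 0.0128, adjusted p = 0.463 with an estimated correlation). Stress genes rose for 1 and fell for 2 of 12, and glycolysis genes rose for 1 and fell for 3 of 19. In the stress list 1 up and 1 down passed adjusted over the list alone (camera adjusted p = 0.276). In the glycolysis list 1 up and 2 down passed adjusted over the list alone (camera adjusted p = 0.504). The glycolysis list had a median log2 fold change of 0.069 and a mean of -0.041, while the direction in camera was down. The pseudokinase Trib3 and the hexokinase Hk2 had log2 fold changes of -2.83 and -1.46. With 1 library left out, calls ended without NPC replicate 1 for Ccnb1, Trib3 and Trp53inp1 (limma adjusted p from 0.0525 to 0.150), without NPC replicate 2 for Ccnb1, Ccnb2, Perp, Trib3 and Trp53inp1 (limma adjusted p from 0.0524 to 0.123) and without mESC replicate 1 for Trib3 (limma adjusted p = 0.187). They were also lost without mESC replicate 2 for Perp and Trib3 (limma adjusted p from 0.0545 to 0.0710). Under some settings Trib3 did not pass (limma adjusted p from 0.0530 to 0.158).

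The last stage was compared with the progenitors to ask which genes change as progenitors mature. Most neuron structure, synapse, glutamatergic and GABAergic genes rose in NC, and cell cycle genes, most glycolysis genes and 7 of 12 retinoic acid genes fell, though no list was called with an estimated correlation. Slc17a6 (ENSMUSG00000030500.5, chromosome 7, 51621830 to 51671125) rose from 0.380 TPM ± 0.272 in NPC to 25.3 ± 5.14 in NC (n = 2 each, log2 fold change 4.25, SE 0.282, limma adjusted p = 0.00286). Mapt, which encodes the axonal microtubule protein tau, rose from 18.6 TPM ± 3.62 to 231 ± 97.9 (log2 fold change 3.51, SE 0.308, limma adjusted p = 0.00296). Cyp26b1 fell from 654 TPM ± 114 to 2.54 ± 0.0360 (log2 fold change -7.52, SE 0.207, limma adjusted p = 0.000173), and Mcm3, a subunit of the replicative helicase, from 192 TPM ± 9.98 to 41.4 ± 7.93 (log2 fold change -2.19, SE 0.163, limma adjusted p = 0.00286). Markers of fibroblasts and mesenchyme rose as well, with Col1a2, a chain of type I collagen, at 6.09 TPM ± 2.47 in NPC and 165 ± 98.9 in NC (log2 fold change 4.45, SE 0.526, limma adjusted p = 0.00402).

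Between NC and NPC, 5123 of 20232 genes changed (limma, adjusted p under 0.05), 3079 higher and 2044 lower in NC. Changes of at least 2-fold numbered 2156 and 1219, and the median log2 fold change of all tested genes was 0.11. The genes that rose made up 60.1% of those changed in TPM, 54.3% after median-of-ratios scaling, 45.5% in FPKM and 47.7% after quantile normalization, so the balance between rising and falling genes turned in the latter 2. The count was 805 without NPC replicate 1, 1454 without NPC replicate 2 and 3170 without NC replicate 2.

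Genes of postmitotic neurons rose in NC for 17 of 20 tested members. In the neuron structure list 19 passed adjusted over the list alone (camera adjusted p = 5.29e-11, adjusted p = 0.277 with an estimated correlation). Stmn2, a regulator of axonal microtubules, rose from 72.6 TPM ± 7.34 to 468 ± 42.0 (log2 fold change 2.67), Dcx, a marker of migrating young neurons, from 56.2 TPM ± 16.8 to 341 ± 16.2 (2.61), and Rbfox3, the nuclear antigen NEUN, from 7.85 TPM ± 2.74 to 49.7 ± 8.68 (2.54). Tubb3 rose from 446 TPM ± 135 to 2023 ± 158 (log2 fold change 2.21, SE 0.251, limma adjusted p = 0.00370) and Map2 from 107 TPM ± 57.6 to 574 ± 45.5 (log2 fold change 2.52, SE 0.344, limma adjusted p = 0.00557). Presynaptic genes rose for 18 of 20, with the vesicle proteins Sv2c, Syt4 and Sv2a changed by 3.60, 3.57 and 2.85 on the log2 scale. In the presynaptic list 20 passed adjusted over the list alone (camera adjusted p = 5.44e-10, adjusted p = 0.277 with an estimated correlation). Neural splicing regulators rose for 8 and fell for 1 of 12, and Celf4 rose from 17.9 TPM ± 9.06 to 148 ± 1.16 (log2 fold change 3.07). In the neural splicing list 8 up and 1 down passed adjusted over the list alone (camera adjusted p = 0.00192, adjusted p = 0.317 with an estimated correlation). Neuronal BAF subunits rose for 5 of 8, led by Actl6b (log2 fold change 2.75). In the BAF neuron list 6 passed adjusted over the list alone (camera adjusted p = 0.00313, adjusted p = 0.288 with an estimated correlation). Proneural genes rose for 9 of 15, among them Igfbpl1 (log2 fold change 2.09) and Nhlh1 (1.56). In the proneural list 9 passed adjusted over the list alone (camera adjusted p = 0.00313, adjusted p = 0.433 with an estimated correlation). The proneural list was not called without NC replicate 1 (camera adjusted p = 0.0708). Nhlh1 was not called without NPC replicate 1 (log2 fold change 1.28). With no filter beyond a TPM above 0 its limma adjusted p was 0.0501.

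Genes of more than 1 transmitter type rose in NC. Glutamatergic genes rose for 15 and fell for 1 of 17 tested, the latter being Camk2a. In the glutamatergic list 15 up and 1 down passed adjusted over the list alone (camera adjusted p = 2.99e-06, adjusted p = 0.288 with an estimated correlation). Gria2 rose from 14.1 TPM ± 5.72 to 90.1 ± 21.5 (log2 fold change 2.62) and the NMDA receptor subunit Grin1 from 2.58 TPM ± 0.329 to 20.01 ± 10.6 (2.46). GABAergic genes rose for 8 of 9 tested. In the GABAergic list 8 passed adjusted over the list alone (camera adjusted p = 0.000139, adjusted p = 0.277 with an estimated correlation). The enzymes of GABA synthesis Gad1 and Gad2 rose from 9.72 TPM ± 3.17 to 95.7 ± 8.40 (log2 fold change 3.20, SE 0.400, limma adjusted p = 0.00444) and from 3.54 TPM ± 1.91 to 74.2 ± 1.70 (log2 fold change 4.12, SE 0.332, limma adjusted p = 0.00293). The neuropeptide gene Npy was listed at 0 in both NPC libraries and at 23.8 ± 5.46 TPM in NC. Markers of Cajal-Retzius cells, which secrete reelin, rose for 6 of 8, with Reln at 13.2 TPM ± 0.518 in NPC and 72.0 ± 9.60 in NC (log2 fold change 2.36). In the Cajal-Retzius list 6 passed adjusted over the list alone (camera adjusted p = 0.00313, adjusted p = 0.288 with an estimated correlation). In NC, Lhx1 stood at 239 ± 33.5, Lhx5 at 148 ± 3.57, Ebf3 at 119 ± 11.4, Nhlh2 at 222 ± 21.3, Cacna2d2 at 82.3 ± 8.66, Ndnf at 14.4 ± 10.7 and Trp73 at 0.414 ± 0.403 TPM. Of the GABAergic and other transmitter genes, Slc32a1 stood there at 69.9 ± 12.02, Calb2 at 46.7 ± 13.3, Th at 33.1 ± 15.5, Ddc at 4.95 ± 1.57 and Slc6a5 at 42.6 ± 12.4 TPM. Markers of cholinergic, monoaminergic, glycinergic and motor neurons rose for 3 and fell for 2 of 9. In the other transmitters list 3 up and 3 down passed adjusted over the list alone (camera adjusted p = 0.971). The other transmitters list had a median log2 fold change of 0.25 and a mean of 0.21, while the direction in camera was down. The glycine transporter Slc6a5 rose (log2 fold change 2.84) and the motor neuron factor Mnx1 fell (-2.68). Of the cortical projection factors 3 rose and 1 fell of 9 tested, and Bcl11b, the subcerebral projection factor CTIP2, rose (log2 fold change 2.52). In the cortical projection list 3 up and 1 down passed adjusted over the list alone (camera adjusted p = 0.654). Grin1 was not called when any 1 NPC or NC library was left out (log2 fold change from 1.92 to 2.995). Bcl11b was not called without NPC replicate 1 (2.015). With no filter beyond a TPM above 0 the limma adjusted p was 0.0613 for Bcl11b and 0.128 for Grin1. With a pseudocount of 5 it was 0.0505 for Grin1.

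**Figure D2:**
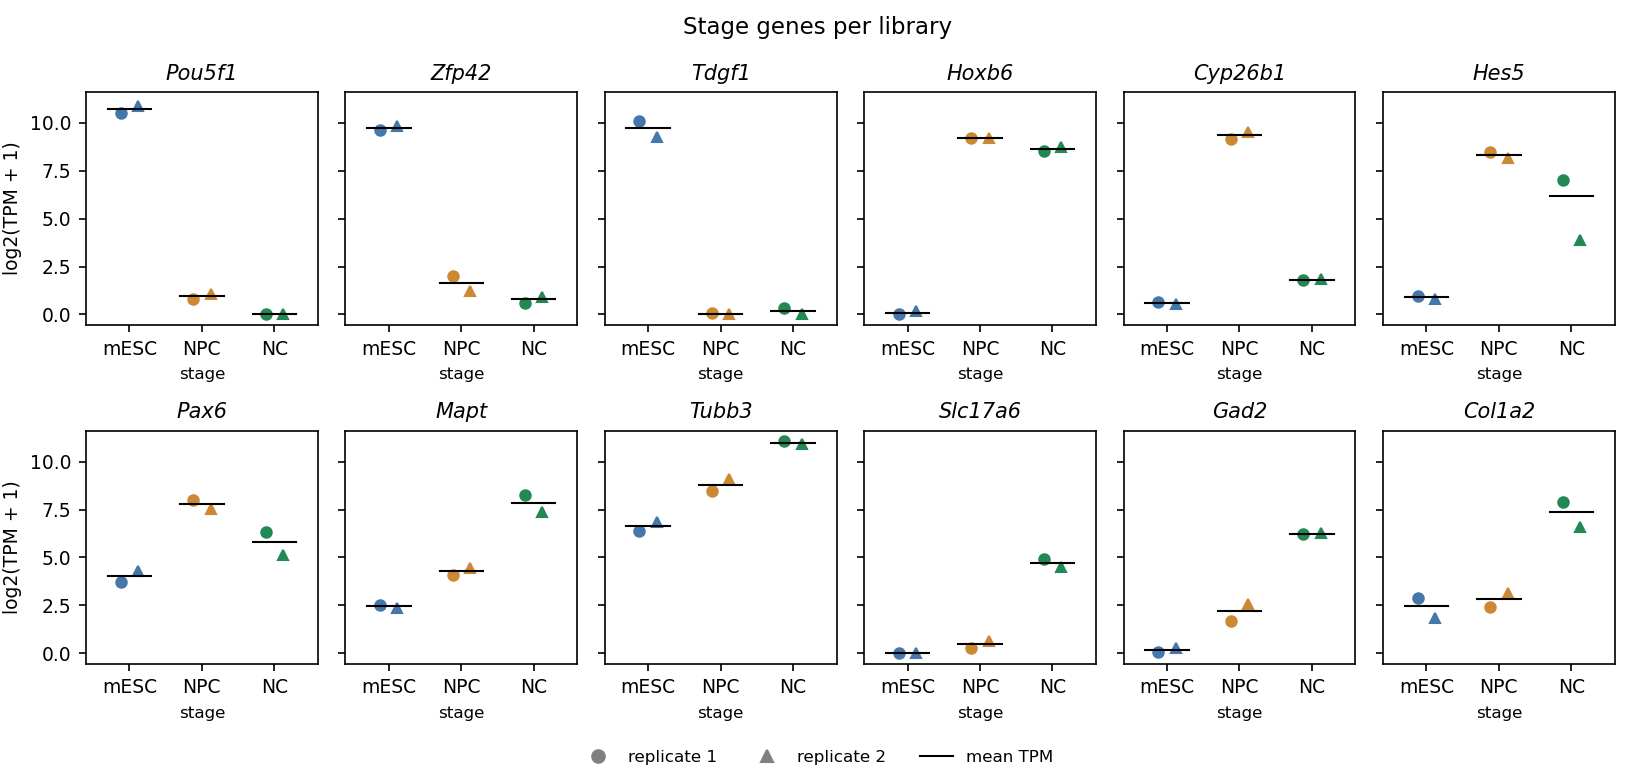
TPM per library, on an axis of log2(TPM + 1), of 12 genes in the 3 stages (points, 2 libraries per stage, and short lines for their mean). Pou5f1 was at 1475 and 1891 TPM in the mESC libraries, Cyp26b1 at 574 and 734 TPM in the NPC libraries and Gad2 at 73.0 and 75.4 TPM in the NC libraries.

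Replication genes fell for 16 of 16 members and mitosis genes for 16 of 16. In the replication list 16 passed adjusted over the list alone (camera adjusted p = 2.49e-13, adjusted p = 0.287 with an estimated correlation). In the mitosis list 16 passed adjusted over the list alone (camera adjusted p = 1.10e-13, adjusted p = 0.277 with an estimated correlation). Mcm5 fell from 206 TPM ± 13.1 to 46.0 ± 11.7 (log2 fold change -2.15) and Top2a, the mitotic topoisomerase, from 357 TPM ± 8.75 to 123 ± 0.646 (-1.53). Targets of p53 rose for 7 of 12, led by the cell cycle inhibitor Cdkn1a, which rose from 72.1 TPM ± 6.35 to 369 ± 143 (log2 fold change 2.29, SE 0.260). In the p53 list 9 passed adjusted over the list alone (camera adjusted p = 0.000542, adjusted p = 0.326 with an estimated correlation). Glycolysis genes fell for 13 and rose for 1 of 19. In the glycolysis list 2 up and 13 down passed adjusted over the list alone (camera adjusted p = 2.66e-05, adjusted p = 0.430 with an estimated correlation). Slc2a1, the glucose transporter GLUT1, fell from 1047 TPM ± 69.6 to 38.2 ± 21.9 (log2 fold change -4.86, SE 0.437), the lactate dehydrogenase Ldha from 1761 TPM ± 167 to 273 ± 163 (-2.82 on the log2 scale), and Eno1, an enolase with the near-identical copy Eno1b, from 2381 TPM ± 140.1 to 523 ± 266 (-2.28). These genes also differed between the NC libraries, where 17 of the 19 glycolysis genes were higher in replicate 1. Activity-regulated genes rose for 5 of 11 tested, with the immediate early factor Egr1 at 2.41 TPM ± 0.470 in NPC and 20.3 ± 3.44 in NC (log2 fold change 2.64). In the activity list 7 passed adjusted over the list alone (camera adjusted p = 0.00303, adjusted p = 0.288 with an estimated correlation). Of the stress genes the most abundant, the endoplasmic reticulum chaperone Hspa5, did not pass the test (405 ± 46.4 and 389 TPM ± 43.2), and the list was not called (camera adjusted p = 0.504) except without NC replicate 1 (camera adjusted p = 0.0209). Calls were lost without NPC replicate 1 for Egr1 and Eno1 (limma adjusted p from 0.0510 to 0.0571).

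Hox genes fell from NPC to NC for 7 of 19, among them Hoxb1 (log2 fold change -2.47). In the HOX list 8 passed adjusted over the list alone (camera adjusted p = 0.00138, adjusted p = 0.277 with an estimated correlation). Retinoic acid genes fell for 7 of 12, and besides Cyp26b1 these included Dhrs3 (255 ± 124 to 7.47 TPM ± 3.81, log2 fold change -4.91) and Cyp26a1 (481 ± 53.4 to 20.5 TPM ± 13.1, -4.63). In the retinoic acid list 3 up and 7 down passed adjusted over the list alone (camera adjusted p = 0.000287, adjusted p = 0.277 with an estimated correlation). Radial glia markers rose for 4 and fell for 5 of 19. In the radial glia list 4 up and 7 down passed adjusted over the list alone (camera adjusted p = 0.0476, adjusted p = 0.414 with an estimated correlation). The radial glia list was not called without mESC replicate 1 (camera adjusted p = 0.0518), without mESC replicate 2 (camera adjusted p = 0.0511), without NPC replicate 2 (camera adjusted p = 0.108) and without NC replicate 2 (camera adjusted p = 0.223), nor under 6 other settings (adjusted p from 0.0570 to 0.137). Pax6 fell from 219 TPM ± 53.3 to 56.0 ± 31.8 (log2 fold change -2.05, SE 0.414, limma adjusted p = 0.0159), while Nes did not pass (106 ± 5.44 and 102 TPM ± 25.1, log2 fold change -0.07, SE 0.253, limma adjusted p = 0.864), nor did Sox2 (79.8 ± 12.03 and 66.9 TPM ± 31.7, log2 fold change -0.33, SE 0.310, limma adjusted p = 0.482). Tnc, the extracellular matrix protein tenascin-C, rose from 0.459 TPM ± 0.161 to 151 ± 91.5 (log2 fold change 6.56, SE 0.461). Fabp7 rose as well (limma adjusted p = 0.0284), with 792 and 164 TPM in NC replicates 1 and 2. Of the pluripotency genes 8 fell and 1 rose of 24, led by Sall4 (48.3 ± 16.3 to 3.84 TPM ± 3.20, log2 fold change -3.49). In the pluripotency list 1 up and 8 down passed adjusted over the list alone (camera adjusted p = 0.00167, adjusted p = 0.277 with an estimated correlation). Pou5f1 was listed at 0 in both NC libraries after 0.920 ± 0.219 TPM in NPC, and Nanog was at 0.161 and 0 TPM in NC. Primed epiblast genes rose for 1 and fell for 1 of 10. In the primed epiblast list 1 up and 1 down passed adjusted over the list alone (camera adjusted p = 0.276). Fabp7 was not called without NC replicate 1 (log2 fold change 1.74). Without NPC replicate 2 this held for Fabp7 and Pax6 (3.36 and -2.30). Without NPC replicate 1 it held for Cyp26a1, Fabp7, Hoxb1 and Pax6 (-4.52, 2.39, -2.19 and -1.80). With no filter beyond a TPM above 0 these genes did not pass (limma adjusted p from 0.0513 to 0.118). Nor did Hoxb1 with a pseudocount of 0.1 (0.0667). Sox2 passed without NC replicate 1 (limma adjusted p = 0.0387).

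The other genes with the largest changes in this comparison were of several kinds. Mab21l2 (2.28 ± 0.534 to 234 TPM ± 90.1, log2 fold change 6.12), which acts in eye development, and Crym, which binds thyroid hormone (1.17 ± 0.237 to 154 TPM ± 159.6, 5.61), rose. So did S100a6 (5.36) and Anxa1 (4.75), which encode calcium-binding proteins, and Postn, a matrix protein of fibroblasts (1.12 ± 0.203 to 72.4 TPM ± 39.97, 5.001). Hk3, a hexokinase gene that overlaps Unc5a on the opposite strand, fell from 48.0 TPM ± 11.9 to 0.336 ± 0.309 (-5.19 on the log2 scale), and Car4, a carbonic anhydrase, from 53.6 TPM ± 24.001 to 0.772 ± 0.394 (-4.89).

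DNA methylation genes fell in NC for 5 and rose for 1 of 10. In the DNA methylation list 1 up and 5 down passed adjusted over the list alone (camera adjusted p = 0.00313, adjusted p = 0.288 with an estimated correlation). Uhrf1, which brings DNMT1 to replicating DNA, fell from 177 TPM ± 13.4 to 62.2 ± 6.77 (log2 fold change -1.49, SE 0.141), Dnmt1 from 208 TPM ± 6.49 to 118 ± 6.95 (log2 fold change -0.81, SE 0.123, limma adjusted p = 0.00715) and Dnmt3b from 19.4 TPM ± 3.10 to 7.23 ± 0.750 (log2 fold change -1.31, SE 0.181, limma adjusted p = 0.00569), while Zfp57 rose from 72.4 TPM ± 17.5 to 288 ± 28.5 (log2 fold change 1.99, SE 0.189). Dnmt3a was at 61.2 TPM ± 4.95 in NPC and 75.3 ± 11.2 in NC (log2 fold change 0.29, SE 0.458, limma adjusted p = 0.686), Tet1 at 18.96 ± 2.66 and 15.1 ± 2.14 TPM (log2 fold change -0.31, SE 0.173, limma adjusted p = 0.239), Tet2 at 45.0 ± 5.79 and 58.8 ± 3.58 TPM (log2 fold change 0.38, SE 0.185, limma adjusted p = 0.178) and Tet3 at 57.6 ± 3.96 and 83.1 ± 16.3 TPM (log2 fold change 0.51, SE 0.182, limma adjusted p = 0.0853), none of them past the threshold. Demethylation genes rose for 3 of 12, and methyl-CpG binding proteins rose for 2 and fell for 1 of 10. In the DNA demethylation list 3 passed adjusted over the list alone (camera adjusted p = 0.867). In the methyl readers list 2 up and 1 down passed adjusted over the list alone (camera adjusted p = 0.647). Imprinted genes rose for 10 and fell for 3 of 22, and the long non-coding RNA Meg3 rose from 449 TPM ± 44.6 to 1876 ± 410.0 (log2 fold change 2.05). In the imprinted list 10 up and 3 down passed adjusted over the list alone (camera adjusted p = 0.109). The imprinted list was called after quantile normalization (camera adjusted p = 0.0146) and without NC replicate 1 (camera adjusted p = 0.0252). Calls were lost without NPC replicate 1 for Dnmt1 and Dnmt3b (limma adjusted p from 0.0646 to 0.0852) and without NPC replicate 2 for Dnmt1 (limma adjusted p = 0.0619). Tet3 passed without NC replicate 1 (limma adjusted p = 0.0498).

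Markers of cell types other than neurons were compared between NPC and NC. Mesenchyme markers rose from NPC to NC for 10 of 12. In the mesenchyme list 10 passed adjusted over the list alone (camera adjusted p = 2.98e-06, adjusted p = 0.277 with an estimated correlation). In NPC and NC, Col3a1 stood at 25.2 ± 15.0 and 373 ± 182 TPM, Col1a1 at 3.51 ± 2.32 and 74.3 ± 26.4 TPM, and Acta2 at 8.83 ± 3.82 and 199 ± 20.5 TPM. Tagln stood at 8.86 ± 1.03 and 131 ± 58.1 TPM, Col6a1 at 10.2 ± 3.64 and 64.3 ± 19.09 TPM and Pdgfrb at 6.81 ± 2.68 and 32.9 ± 19.7 TPM. Dcn, the matrix proteoglycan decorin, was at 0 and 0.504 TPM in the NPC libraries and 21.3 ± 1.61 TPM in NC. Fn1 (597 ± 278 in mESC, 164 ± 15.7 in NPC and 326 TPM ± 243 in NC) and Twist1 (13.0 ± 5.58 and 12.1 TPM ± 4.11) were the members that did not pass. Neural crest markers rose for 5 and fell for 1 of 10. In the neural crest list 7 up and 1 down passed adjusted over the list alone (camera adjusted p = 0.181). In NPC and NC, Tfap2b stood at 18.3 ± 11.9 and 82.0 ± 34.3 TPM, Tfap2a at 7.67 ± 4.30 and 36.0 ± 20.1 TPM, Pax3 at 35.6 ± 20.8 and 31.5 ± 4.19 TPM and Pax7 at 29.8 ± 7.21 and 2.46 ± 2.31 TPM. Likewise Ngfr stood at 19.2 ± 1.46 and 46.7 ± 22.8 TPM, Ets1 at 7.03 ± 0.237 and 17.0 ± 7.10 TPM and Foxd3 at 5.61 ± 0.489 and 23.7 ± 17.1 TPM. Endoderm markers fell for 2 of 9 tested. In the endoderm list 3 passed adjusted over the list alone (camera adjusted p = 0.00972, adjusted p = 0.549 with an estimated correlation). The endoderm list was not called without NPC replicate 1 (camera adjusted p = 0.0704) and without NC replicate 1 (camera adjusted p = 0.0693). Sox17 went from 65.6 TPM ± 17.2 to 9.14 ± 3.09 (log2 fold change -2.73), and Gata4 was at 49.1 ± 12.6 and 13.3 ± 6.58 TPM, Foxa2 at 20.8 ± 4.89 and 5.55 ± 3.60 TPM, Dab2 at 60.5 ± 19.6 and 20.2 ± 13.8 TPM and Gata6 at 13.7 ± 3.22 and 8.88 ± 5.30 TPM. Endoderm markers also differed between the mESC libraries, with Dab2 at 109.7 and 24.9 TPM, Gata4 at 38.9 and 8.42 TPM and Sox17 at 22.6 and 5.48 TPM in replicates 1 and 2. Mesoderm markers rose for 1 and fell for 1 of 8 tested, with Meox1 at 17.1 ± 0.242 and 4.18 ± 1.41 TPM and Pecam1, at 27.2 TPM ± 10.6 in mESC, at 1.55 ± 0.0215 and 0.781 ± 0.924 TPM. In the mesoderm list 1 up and 1 down passed adjusted over the list alone (camera adjusted p = 0.176). The mesoderm list was called with a filter at TPM of at least 5 (camera adjusted p = 0.0491) and without NC replicate 2 (camera adjusted p = 0.00401). Astrocyte markers rose for 1 and fell for 2 of 7 tested. In the astrocyte list 2 up and 2 down passed adjusted over the list alone (camera adjusted p = 0.914). Its median log2 fold change was 0.42 (mean 0.66), while camera pointed down. The glutamate transporter Slc1a2 rose from 25.5 TPM ± 6.69 to 70.1 ± 7.49, Gja1 fell from 122 TPM ± 1.30 to 55.0 ± 5.91 and Glul from 143 TPM ± 24.9 to 84.6 ± 23.3, and Fgfr3 was at 91.9 ± 1.66 and 71.9 ± 42.8 TPM. The NC libraries differed most in this list, with Aldoc at 98.6 and 3.02 TPM, Aldh1l1 at 59.3 and 1.89 TPM and Sparcl1 at 106 and 34.0 TPM in replicates 1 and 2, and Gfap, below the test's filter, at 9.72 and 0.598 TPM after 0.172 ± 0.0254 TPM in mESC and 0.390 ± 0.195 TPM in NPC. Oligodendrocyte lineage genes rose for 2 and fell for 2 of 8 tested, with Mbp at 21.5 ± 5.05, Cnp at 24.6 ± 6.29 and Pdgfra at 20.5 ± 14.0 TPM in NC. In the oligodendrocyte list 2 up and 2 down passed adjusted over the list alone (camera adjusted p = 0.895). Its median log2 fold change was 0.13 (mean 0.072), while camera pointed down. Of the microglia and blood markers 2 passed the filter, Csf1r at 1.85 ± 0.901 and Tmem119 at 4.92 ± 1.40 TPM in NC. Sox17 was not called when any 1 NPC or NC library was left out (log2 fold change from -3.04 to -2.41). With no filter beyond a TPM above 0 its limma adjusted p was 0.0910.

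The ends of the differentiation, NC and mESC, were compared to give the change over both steps. Most tested genes of neurons rose and all tested pluripotency genes fell. Robo3, a receptor that guides commissural axons, rose from 0.356 TPM ± 0.0550 in mESC to 647 ± 259 in NC (n = 2 each, log2 fold change 8.84, SE 0.336, limma adjusted p = 1.58e-05) and Miat from 0.648 TPM ± 0.296 to 915 ± 147 (log2 fold change 9.12, SE 0.225, limma adjusted p = 6.94e-06). Dcx, Sst and Fabp7 were listed at 0 in both mESC libraries and stood in NC at 341 ± 16.2, 438 ± 265 and 478 ± 444 TPM (limma adjusted p = 8.86e-06, 2.76e-05 and 0.000143). Dppa5a, a pluripotency marker, fell from 1579 TPM ± 166 to 1.12 ± 0.772 (log2 fold change -9.58, SE 0.274, limma adjusted p = 9.08e-06), Zfp42 from 853 TPM ± 88.8 to 0.724 ± 0.257 (log2 fold change -8.96, SE 0.290) and Trh from 610.7 TPM ± 74.6 to 0.436 ± 0.00571 (log2 fold change -8.73, SE 0.206).

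Of 20232 genes tested, 12118 changed between NC and mESC (limma, adjusted p under 0.05), 7656 higher and 4462 lower in NC, with changes of at least 2-fold in 5874 and 3025. The median log2 fold change of all tested genes was 0.31, and 0.03 after median-of-ratios scaling. The share of changed genes that rose was 63.2% in TPM, 51.9% after median-of-ratios scaling, 51.7% in FPKM and 47.2% after quantile normalization.

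The 24 of 24 pluripotency genes that fell included Tdgf1 (852 TPM ± 346.1 in mESC and 0.275 and 0 TPM in NC, log2 fold change -9.498, SE 0.326) and Nanog (0.161 and 0 TPM in NC, log2 fold change -7.78, SE 0.245, limma adjusted p = 1.02e-05). In the pluripotency list 24 passed adjusted over the list alone (camera adjusted p = 2.80e-18, adjusted p = 0.104 with an estimated correlation). Pou5f1 and Tdh, which encodes threonine dehydrogenase, were listed at 0 in both NC libraries (limma adjusted p = 6.94e-06 and 6.94e-06). Neuron structure genes rose for 19 and fell for 1 of 20, with Map2 up from 3.75 TPM ± 0.181 to 574 ± 45.5 (log2 fold change 6.92, SE 0.344, limma adjusted p = 2.82e-05) and Tubb3 from 99.98 TPM ± 23.1 to 2023 ± 158 (log2 fold change 4.34, SE 0.251, limma adjusted p = 4.16e-05). In the neuron structure list 19 up and 1 down passed adjusted over the list alone (camera adjusted p = 5.44e-08, adjusted p = 0.277 with an estimated correlation). Presynaptic genes rose for 20 of 20, glutamatergic genes for 14 of 17 and GABAergic genes for 8 of 9 tested. Adjusted over the list alone 20, 14 and 8 of them rose and 1 GABAergic gene fell. The camera adjusted p was 2.09e-07, 0.000188 and 0.00429, and 0.277, 0.323 and 0.288 with an estimated correlation. Slc17a7 of the glutamatergic list did not pass (2.46 ± 0.557 and 2.45 TPM ± 1.07, log2 fold change -0.03, limma adjusted p = 0.938). It rose from NPC to NC (log2 fold change 1.13). Slc17a6 was listed at 0 in both mESC libraries and at 25.3 ± 5.14 TPM in NC (limma adjusted p = 4.61e-05), and Gad1 rose from 9.15 TPM ± 5.49 to 95.7 ± 8.40 (log2 fold change 3.36, SE 0.400, limma adjusted p = 0.000628). Cortical projection factors rose for 8 of 9 tested, with Bcl11b at 14.4 TPM ± 6.25 in NC (log2 fold change 2.93). In the cortical projection list 8 passed adjusted over the list alone (camera adjusted p = 0.00104, adjusted p = 0.277 with an estimated correlation). Hox genes were above mESC for 18 of 19, with Hoxb6 at 403 TPM ± 44.4 in NC (log2 fold change 8.56). In the HOX list 18 passed adjusted over the list alone (camera adjusted p = 2.11e-08, adjusted p = 0.167 with an estimated correlation). Mesenchyme markers were higher than in mESC for 11 of 12. In the mesenchyme list 11 passed adjusted over the list alone (camera adjusted p = 0.00168, adjusted p = 0.288 with an estimated correlation). Pax6 (log2 fold change 1.70, SE 0.414, limma adjusted p = 0.0118) and Nes (log2 fold change 3.38, SE 0.253, limma adjusted p = 0.000101) were higher in NC than in mESC and Sox2 was lower (log2 fold change -2.02, SE 0.310, limma adjusted p = 0.00182). Pax6 was not called without mESC replicate 1 (log2 fold change 1.41). With no filter beyond a TPM above 0 its limma adjusted p was 0.0595.

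DNA methylation genes were lower in NC than in mESC for 8 and higher for 1 of 10. In the DNA methylation list 1 up and 8 down passed adjusted over the list alone (camera adjusted p = 0.000108, adjusted p = 0.277 with an estimated correlation). Dnmt1 fell (log2 fold change -0.82, SE 0.123, limma adjusted p = 0.00164), Dnmt3b fell to 7.23 TPM ± 0.750 (log2 fold change -3.78, SE 0.181, limma adjusted p = 2.66e-05) and Dnmt3a did not pass (log2 fold change -0.09, SE 0.458, limma adjusted p = 0.881). For Dnmt3a the log2 fold change was -0.87 without mESC replicate 1 and 0.69 without mESC replicate 2, where it passed in opposite directions (limma adjusted p = 0.0132 and 0.0318), and 0.063 without NC replicate 2, where it did not pass. Tet1 fell (log2 fold change -3.63, SE 0.173, limma adjusted p = 2.63e-05), Tet2 fell (log2 fold change -0.85, SE 0.185, limma adjusted p = 0.00762) and Tet3 rose (log2 fold change 3.10, SE 0.182, limma adjusted p = 4.28e-05). Germline genes fell for 9 of 10 tested, and imprinted genes rose for 18 and fell for 2 of 22, with Nnat, a neuronatin gene of the brain, up from 60.7 TPM ± 1.69 to 2588 ± 902 (log2 fold change 5.34) and Igf2 up to 875 TPM ± 5.69 (5.40). In the germline list 9 passed adjusted over the list alone (camera adjusted p = 3.40e-05, adjusted p = 0.277 with an estimated correlation). In the imprinted list 18 up and 2 down passed adjusted over the list alone (camera adjusted p = 0.000542, adjusted p = 0.277 with an estimated correlation). Dnmt3a passed without mESC replicate 1 (limma adjusted p = 0.0132).

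**Figure D3:**
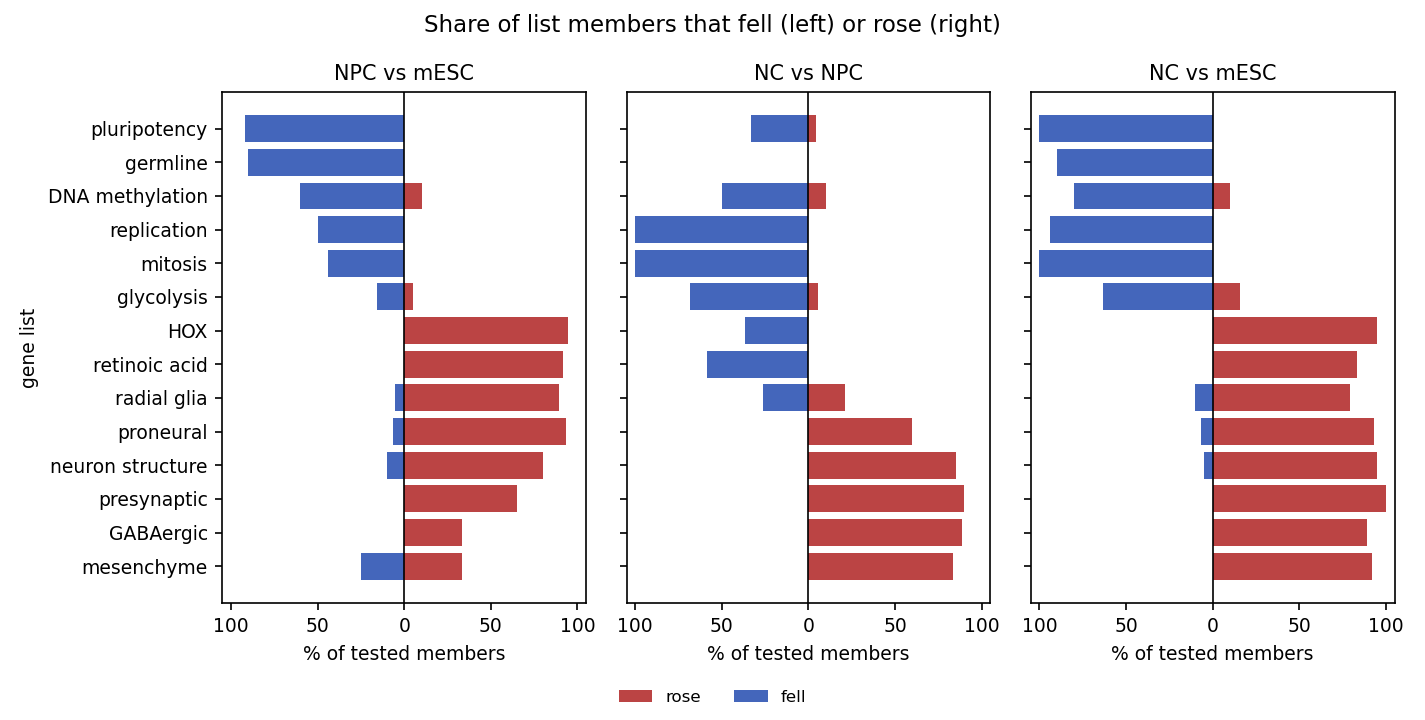
Percentage of tested members of 14 gene lists that rose (bars to the right) or fell (bars to the left) in each of the 3 comparisons, by limma at an adjusted p under 0.05. From NPC to NC 16 of 16 replication and 16 of 16 mitosis genes fell, and from mESC to NPC 18 of 19 Hox genes rose.

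Genes that were higher in NPC than in both other stages numbered 501. Both calls use the NPC libraries. Independent lists of the sizes of the genes that rose and then fell would share 532, and none of 100 simulations with no effect gave such a gene by limma. The count was 87 without NPC replicate 1 and 119 without NPC replicate 2. Of 12 retinoic acid genes tested 7 were among them, of 19 Hox genes 7 and of 19 radial glia markers 5. Of all tested genes 2.48% were (Fisher's exact test, one-sided, adjusted p = 1.36e-07, 3.73e-06 and 0.000929). They included Cyp26a1, Cyp26b1, Rarb, Hoxb1, Hoxb4, Hoxb6, Pax6 and Sox3. The test takes genes as independent, so its p can be too small. In these lists 11, 18 and 17 members rose from mESC to NPC, which by itself raises the share. Genes that rose in both steps numbered 1391 (802 for independent lists), genes that fell in both 375 (286), and genes that fell and then rose 281 (431).

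The make-up of the libraries differed between stages. Ribosomal protein genes held 13.3% ± 0.514 of all TPM in mESC, 12.3% ± 0.826 in NPC and 7.17% ± 0.341 in NC (SD, n = 2). Replication-dependent histone genes held 0.163% ± 0.0253, 0.148% ± 0.0190 and 0.0546% ± 0.000175, and the 10 most abundant genes 4.803% ± 0.140, 4.23% ± 0.303 and 5.39% ± 0.777. Annotated protein-coding genes held 81.1% ± 0.348 in mESC, 82.6% ± 0.758 in NPC and 83.8% ± 0.0866 in NC. These shares were not tested.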

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

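All alternatives were planned before the data were examined except the restriction to protein-coding genes, which was chosen after they were seen. Of 147 gene results in the report 137 were called, and over the alternatives their calls were kept in 2510 instances, lost with the same direction in 62 and reversed in 0. Of 70 gene list results 52 were called at the preset correlation, with 905 instances kept, 83 lost, of which the estimated correlation accounts for 52, and 0 reversed. Results that were not called kept their side and direction in 174 instances for genes and 312 for lists, passed the threshold in 4 and 6, and changed direction in 12 and 24. No gene called in the report's fit was called in the opposite direction under any alternative. Depth was similar, between 1.57 and 2.27 Gb of aligned bases. The 43 of 100 simulated genes recovered at a log2 fold of 1 do not give the rate in the data, where more genes changed.

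With a replicate block, 7368 genes changed between NPC and mESC, 4247 between NC and NPC and 11575 between NC and mESC, 428 were higher in NPC than in both other stages and 62 list tests were called. The differences between replicates 1 and 2 correlated across genes at 0.045 between mESC and NPC, -0.082 between mESC and NC and -0.070 between NPC and NC, where genes are not independent replicates. Between NC and NPC 3166 genes changed with no filter beyond a TPM above 0, where more genes are tested, and 3375 changed with an absolute log2 fold change of at least 1, which is a stricter call. The number of called list tests was 0 with camera at an estimated correlation, where 17 had an unadjusted p under 0.05. There the test rests on the 3 residual degrees of freedom, so this count is not a measure of correlation alone.

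Leaving out each library in turn gave 4138 to 8680 changed genes between NPC and mESC, 805 to 5264 between NC and NPC and 9290 to 10873 between NC and mESC, 87 to 475 genes higher in NPC than in both other stages and 58 to 62 called list tests. The group left with 1 library is then assumed to vary like the other groups. The lowest counts came without NPC replicate 2 (4138) for NPC against mESC and without NPC replicate 1 for NC against NPC (805) and for the genes highest in NPC (87), and the cause was not tested. Without NPC replicate 1, 4733 genes changed between NPC and mESC. Without NPC replicate 2 the counts were 1454 between NC and NPC and 119 highest in NPC, and without NC replicate 2 3170 changed between NC and NPC.

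The direction of some results that were not called changed, and the cause was not tested. For lists the value is the median log2 fold change of the members and the direction is that of camera, which can differ from the sign of the median. With a pseudocount of 0.1 this was so for the other transmitters list in NC against NPC (0.27). With no filter beyond a TPM above 0 this was so for the BAF progenitor list in NPC against mESC (0.047), the astrocyte list in NC against NPC (0.32) and the other transmitters list in NC against NPC (0.15). With a filter at 5 TPM this was so for the oligodendrocyte list in NC against NPC (0.13). After median-of-ratios scaling this was so for the other transmitters list in NC against NPC (0.18) and Gad1 in NPC against mESC (-0.044). After quantile normalization this was so for the BAF progenitor list in NPC against mESC (0.11), the astrocyte list in NC against NPC (0.34), the glycolysis list in NPC against mESC (0.086), the other transmitters list in NC against NPC (0.043), Dnmt1 in NPC against mESC (0.089) and Gad1 in NPC against mESC (-0.23). Without ribosomal protein and the most abundant genes this was so for the other transmitters list in NC against NPC (0.21). In FPKM this was so for the astrocyte list in NC against NPC (0.38) and the oligodendrocyte list in NC against NPC (-0.011). With a replicate block this was so for the other transmitters list in NC against NPC (0.25). With protein-coding genes only this was so for the DNA demethylation list in NC against NPC (0.19). With each library left out in turn, the value ranged for Dnmt1 in NPC against mESC from -0.043 to 0.021, Dnmt3a in NC against mESC from -0.87 to 0.69, Dnmt3a in NPC against mESC from -1.16 to 0.41 and Gad1 in NPC against mESC from -0.42 to 0.74. It ranged for Nes in NC against NPC from -0.32 to 0.18, Sox2 in NC against NPC from -0.82 to 0.17, the BAF progenitor list in NPC against mESC from -0.046 to 0.081 and the DNA demethylation list in NC against NPC from 0.033 to 0.38. Further ranges were those for the astrocyte list in NC against NPC from -1.03 to 1.33, the cortical projection list in NC against NPC from -0.049 to 0.25, the oligodendrocyte list in NC against NPC from -0.13 to 0.36, the other transmitters list in NC against NPC from -0.44 to 0.47 and the stress list in NC against NPC from -0.13 to 0.96. The log2 fold change of Dnmt3a without mESC replicate 2 was 0.41 in NPC against mESC and 0.69 in NC against mESC (limma adjusted p = 0.174 and 0.0318), and without NC replicate 2 it was 0.063 in NC against mESC (limma adjusted p = 0.941).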

Other observations

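The 4 further marker lists below were written after the results above were seen and before their own values were seen, except for the forebrain list, of which 13 of 16 members are on an earlier list. The members named were chosen after, and of the tests only that on the depth of the NC libraries was chosen after its result was seen.

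Most tested genes of hindbrain and spinal cord interneurons were higher in NC than in mESC. Of 16 tested members of a list of 17, none on an earlier list, 8 rose from mESC to NPC and 11 rose and 1 fell from NPC to NC. In NC against mESC 13 rose (camera adjusted p = 0.000335, p = 0.0964 with an estimated correlation), after an adjusted p of 0.00157 for NC against NPC (p = 0.128 with an estimated correlation) and 0.00567 for NPC against mESC (p = 0.165 with an estimated correlation). Pax2, a factor of inhibitory interneurons, stood at 0.126 TPM ± 0.0398 in mESC, 26.4 ± 4.004 in NPC and 108 ± 2.54 in NC (NC against NPC log2 fold change 2.00, limma adjusted p = 0.00323). Its relative Pax8 stood at 0.979 ± 0.125, 14.5 ± 3.80 and 84.3 ± 0.611 TPM. Lmx1b, a factor of dorsal spinal and serotonergic neurons, stood at 0.313 ± 0.0789, 2.16 ± 0.258 and 37.9 ± 1.55 TPM. Lbx1, a factor of dorsal spinal interneurons, was listed at 0 in both mESC libraries and stood at 11.3 ± 7.15 and 53.03 ± 18.4 TPM in NPC and NC. The gene that fell was Ptf1a, at 1.96 and 8.43 TPM in the NPC libraries and 0 and 0.274 TPM in NC.

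Of 16 forebrain genes, 13 from earlier lists, 0 reached a mean of 10 TPM in any stage. The cortical projection factors Neurod2, Bcl11b and Bhlhe22, not on the list, stood at 10.5 ± 14.5, 14.4 ± 6.25 and 48.1 ± 16.1 TPM in NC. Of its 5 tested members 2, Emx2 and Dlx1, rose from mESC to NC, 1 from NPC to NC and 2 from mESC to NPC. No test called the list (camera adjusted p = 0.622, 0.561 and 0.561). In the NC libraries, Tbr1 stood at 0.401 TPM ± 0.143 and Neurod6 at 14.7 and 0 TPM.

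Mesenchyme markers were higher in NC than in NPC, and a candidate explanation is cells of another type in the NC cultures. In a second list of 24 genes abundant in fibroblasts, none of them on an earlier list, 70.8% rose (17 genes, camera adjusted p = 9.37e-06, p = 0.0862 with an estimated correlation), and 8 rose from mESC to NPC and 19 from mESC to NC (camera adjusted p = 0.561 and 0.000335, p = 0.736 and 0.139 with an estimated correlation). Of these 24 genes, mESC also held 14 and NPC 16 at a mean of at least 10 TPM, and among those not called were the abundant Sparc at 572 TPM ± 185 in NPC and 499.6 ± 30.04 in NC, Serpinh1 at 389.6 ± 27.5 and 445 ± 17.5, and Col4a1 and Col4a2, which were lower in NC (716 ± 213 to 283 ± 2.40 and 427 ± 132 to 173 ± 10.6, log2 fold change -1.30 and -1.27). Scaling between the libraries as the whole cause is argued against by the median log2 fold change of the called markers, which was 3.99 as deposited and 3.90 after median-of-ratios scaling (median SE 0.403, 10 of 10 called). Expression of these genes by the differentiating cells themselves, the difference in stage that the design names, stays open and was not tested.

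Astrocyte markers differed between the 2 NC libraries, with Aldoc, Aldh1l1, Gfap and Sparcl1 higher in replicate 1 and Slc1a2 and Gja1 lower. The 1.19-fold difference in depth as the cause is argued against, since the median log2 difference of a second list of 20 astrocyte genes, 1.65 over 14 tested (SD 1.66), was reached by 0 of 1000 draws of genes of matched level (-0.44 to 0.46). Astrocyte-like cells in NC replicate 1 may account for part of it, since 11 of these 14 were higher there, though that list was not called in any comparison (camera adjusted p = 0.871, 0.561 and 0.561). Of its 6 genes at 50 TPM or more in either NC library, replicates 1 and 2 held Cst3 at 341 and 183, Ttyh1 at 268 and 14.8, Clu at 94.3 and 171, Atp1b2 at 58.9 and 5.61, Apoe at 56.0 and 48.6 and F3 at 24.7 and 63.2 TPM. Of the 20 genes 7 in mESC and 5 in NPC had a mean of at least 10 TPM, which can hide a small share of such cells. Higher in replicate 1 were also 17 of 19 glycolysis but 0 of 8 mesoderm genes.

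The 7 gene models at 24611535 to 24616197 on chromosome 1 held 2.01% ± 0.0718 of all TPM in mESC, 1.66% ± 0.144 in NPC and 3.46% ± 1.14 in NC. Reads of mitochondrial transcripts placed on this nuclear copy are a likely source, since the models match mitochondrial transcripts at 99.71% to 100% identity while all 37 mitochondrial genes are listed at 0. Transcription of the nuclear copy itself was not tested.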
